A study of Mus musculus with 7 samples.

How the data were processed

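Nuclei were isolated from snap-frozen skeletal muscle of the lower hindlimb of C57BL6J mice, sorted by FACS and run on the 10x Multiome kit, which measures RNA and open chromatin (ATAC) in the same nucleus. The sciatic nerve of 1 leg was resected, and the mice then received a daily intraperitoneal injection of an inhibitor of 15-PGDH, the enzyme that starts the breakdown of prostaglandin E2, or vehicle. Muscle was taken on day 14. The titles and treatment protocol in the labels speak of transection or resection, while the sample descriptions speak of a crush, and the word transection is used here. The 7 libraries form 4 groups: 1 vehicle contralateral library, which the labels give as a pool of samples 1 and 2, and 2 libraries each of vehicle denervated, inhibitor contralateral and inhibitor denervated muscle. The labels do not say whether replicates came from separate animals or whether legs with the same sample number came from the same animal, so the p-values measure the spread between these libraries, which may be technical.

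The deposited matrices hold counts per feature and barcode: UMI counts for genes and counts of transposition events for ATAC peaks. Cell Ranger ARC made them on the mm10 build, per the submitters' processing notes, with the version not given in the sources used here. The values are whole numbers without normalization, and the names of the deposited files say that barcodes had been filtered. Each matrix lists 32285 genes. The peaks differ between the deposited matrices, from 44144 to 59192 per library, so the authors called them per library. In 1 vehicle denervated and 1 inhibitor denervated library, 1 peak line has no name, and its counts, 0.00186% and 0.0022% of the library's peak counts, were not used here. Gene positions and peak annotation come from GENCODE mouse release M21, which uses the GRCm38 (mm10) assembly.

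Nuclei were kept with at least 500 UMIs, at least 200 genes and at most 5% mitochondrial UMIs. Doublet scores were computed with Scrublet in scanpy 1.11.5. Its automatic threshold called at most 0.684% of the nuclei of any library, so the highest-scoring nuclei were removed instead, at a rate of 0.8% per 1000 barcodes, a choice made after seeing the scores. Counts were scaled to a common total per nucleus and log-transformed. The 3000 most variable genes gave 30 principal components and a graph of 15 neighbours, which was clustered with the Leiden method in igraph 0.11.9 at a resolution of 1. No correction between libraries was applied. Clusters were named from marker lists of muscle cell types when the mean log2 ratio of a list's genes over the other clusters was at least 1.5 with at least 3 genes above 1. Classes are therefore written as X-like. The rule for myofibre-like clusters, at least 3 markers more than 1.5-fold above the non-myofibre clusters and a best score of another class under 0.3, was set after the clusters were seen. It left out a cluster with mixed markers. A named cluster lost its name if its 10 leading genes held more markers of another class than of its own. It also lost it if its UMI counts were low and those genes held no marker of its class. A cluster led by Ankrd1 and Csrp3 was left unnamed by these checks. The share of both clusters per group is given in the results.

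Counts were summed over the nuclei of a class in each library. Genes were filtered with filterByExpr, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with p-values adjusted by the Benjamini-Hochberg method over all genes tested and a threshold of 0.05. The effect of the leg over both treatments used treatment as a covariate, and the other comparisons used 1 mean per group. The lone vehicle contralateral library carries no estimate of its own spread and was assumed to vary like the other groups, and its 2 comparisons rest on 1 pooled library. Errors beside log2 changes are approximate standard errors, the absolute log2 change divided by the square root of the test's F statistic. Levels are CPM, the summed counts scaled by the library's normalized size as edgeR computes them, given as mean ± SD over libraries. Other classes were tested where every library held at least 20 nuclei. Shares of nuclei per class were tested in the same way, with the number of kept nuclei as offset. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over 19 lists per comparison.

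ATAC peaks of all libraries were merged where they overlapped by at least 1 bp into 95906 regions. The 25815 regions with a peak in every library were counted over the myofibre-like nuclei and tested like genes. Coordinates are counted from 1. A region's counts sum over the part covered by each library's own peaks. The covered length summed over the shared regions differed little between libraries, from 22495992 to 22677829 bp.

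The groups, comparisons, tests, marker lists, gene lists and the rule for named genes were fixed before the data were examined. The rule names, per comparison in myofibre-like nuclei, the 10 genes with the highest and the 10 with the lowest log2 change among those past the threshold, with at least 20 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted and clone-named genes. It adds up to 4 members with the smallest p from each gene list, and Hpgd, Ptger4, Chrna1, Musk, Myog, Fbxo32, Trim63 and Myh4. For other classes it names 5 genes per direction, and for accessibility up to 5 regions on or within 1 kb of named genes. A fold against a group without counts is a lower bound at the floor of 3 counts over the group. For a group with 1 to 3 counts, the ratio of the summed counts scaled to the libraries' totals is given with its 95% counting interval. Intervals and floors cover counting error only. Shares of nuclei have exact (Clopper-Pearson) 95% intervals.

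The tests were run on simulated counts drawn from the real means and library sizes. Of the genes simulated with a 4-fold change, the test called 73.1% for inhibitor against vehicle in denervated muscle, 81.7% for denervated against contralateral muscle with the inhibitor, 53.3% for that comparison with vehicle and 53.8% for inhibitor against vehicle in contralateral muscle. At a 2-fold change it called 18.5%, 25%, 7.87% and 7.78%. Of the genes called, 8.6%, 8.33%, 8.33% and 1.72% had been simulated without a change, in the same order. This share lay above the threshold set for the adjusted p in all but the last comparison. The 4 simulations tested 9673, 9673, 9678 and 9660 genes. For ATAC regions, with 25810 tested in each simulation, the recovery at a 2-fold change was 78%, 86%, 64% and 73% in the same order. Of the regions called, 7.9%, 10.6%, 6.02% and 7.65% had been simulated without a change, each share above that threshold.

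The alternatives tried were DESeq2's size factors, the Wald test of DESeq2 1.42.0, no filter and a stricter filter on low counts, leaving out in turn each library of a group with 2, the replicate number as a block, a minimum of 1000 UMIs, doublets kept, counts over all nuclei, the libraries of the compared groups only, and, for shares, a clustering resolution of 2. Added after seeing the data were a minimum of 200 UMIs, resolution 2 for the other results, leaving out the vehicle contralateral library, leaving out libraries in the other classes, the Ankrd1 and Csrp3 cluster or the mixed-marker cluster put back, the Atf3 and Klhl40 cluster taken out, nuclei removed at random, ribosomal-RNA-like transcripts removed, counts thinned to the smallest library, single clusters of myofibre-like nuclei with at least 20 nuclei in every library of a leg, and shares with the unnamed clusters counted as myofibre-like. For ATAC they were regions with a peak in at least 4 libraries and DESeq2 size factors, with a block there and in the other classes and the covered length as offset added after seeing the data. Results for some genes that the naming rule picks are not reported here.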

Results

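RNA and open chromatin were measured in single nuclei of mouse lower-hindlimb muscle 14 days after the sciatic nerve of 1 leg had been transected. The contralateral leg of the same design stayed innervated, and mice received an inhibitor of 15-PGDH or vehicle. Of the 7 libraries, 1 is vehicle contralateral (a pool of samples 1 and 2), and 2 each are vehicle denervated, inhibitor contralateral and inhibitor denervated. They hold 16276 barcodes, from 891 in an inhibitor denervated library to 4459 in an inhibitor contralateral library. Depth was uneven. The vehicle contralateral library had 1368706 UMIs in all, the vehicle denervated libraries 2685240 and 4250093, the inhibitor contralateral libraries 8663808 and 10742883, and the inhibitor denervated libraries 3022900 and 1607038. The filters kept 12707 nuclei, 47.2% of the barcodes in the vehicle contralateral library and between 58.8% and 91.9% in the others. Myofibre-like nuclei numbered 7957. They carried 637140 UMIs in the vehicle contralateral library, 491329 and 1300480 in the vehicle denervated, 6363806 and 8301931 in the inhibitor contralateral, and 1340195 and 693827 in the inhibitor denervated libraries.

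Myofibre-like nuclei made up 72.2% to 78.2% of the nuclei in the 3 contralateral libraries and 37.6% to 45.8% in the 4 denervated libraries. Over both treatments this share fell by 0.90 on the log2 scale, while macrophage-like nuclei rose by 1.55, as did the 2 unnamed clusters described below, the mixed-marker one by 3.43 and the one led by Ankrd1 and Csrp3 by 4.95 (adjusted p = 0.0384 for each, edgeR quasi-likelihood test on numbers of nuclei, Benjamini-Hochberg over 12 classes). The fall largely mirrors nuclei that the naming rule left out of the class. With the mixed-marker cluster counted as myofibre-like, the class held 72.7% to 88.3% of contralateral, 81.2% and 70.4% of vehicle denervated and 47.5% and 63.3% of inhibitor denervated libraries, and its change of -0.36 did not pass (adjusted p = 0.454), nor did that of macrophage-like nuclei (adjusted p = 0.0536; same test over 11 classes). With both unnamed clusters counted the change was -0.20 (adjusted p = 0.621), and macrophage-like nuclei passed (adjusted p = 0.0447; same test over 10 classes). Macrophage-like nuclei were 1.59% of the vehicle contralateral library and 2.05% and 3.32% of the vehicle denervated libraries. With the inhibitor they were 1.73% and 1.17% in contralateral and 7.08% and 4.86% in denervated muscle. Inhibitor against vehicle did not pass for them in denervated muscle (log2 change 1.15, adjusted p = 0.178). At a clustering resolution of 2 that change was 0.50 (adjusted p = 0.429; edgeR quasi-likelihood test on numbers of nuclei, Benjamini-Hochberg). Neuromuscular-junction-like nuclei were 0.227% to 0.928% of contralateral and 1.11% to 1.88% of denervated libraries (log2 change 1.44, adjusted p = 0.0515, same test). Satellite-cell-like nuclei were 0 of 882 in the vehicle contralateral library, which allows a share of up to 0.417%, and 2 and 3 nuclei in the vehicle denervated libraries. The inhibitor libraries held 84 of 3232 and 86 of 4009 nuclei in contralateral and 21 of 904 and 2 of 638 in denervated muscle. The share did not differ between the legs with the inhibitor (log2 change -0.77, adjusted p = 0.578, same test). The adjusted p for inhibitor against vehicle was 0.0564 in contralateral and 0.148 in denervated muscle (same test). These numbers depend on the minimum of 500 UMIs: with 200 UMIs, 9 of 1489 vehicle contralateral nuclei were satellite-cell-like and 13 and 33 in the vehicle denervated libraries. The contralateral comparison then passed (adjusted p = 0.0326), as it did at a clustering resolution of 2 (adjusted p = 0.0403), but not with 1000 UMIs (adjusted p = 0.714) or with doublet calls kept (adjusted p = 0.075; same test, Benjamini-Hochberg). Sorting and pooling of muscles can set such shares, and the calls for the leg were not stable. With at least 1000 UMIs per nucleus neither myofibre-like (adjusted p = 0.154) nor macrophage-like nuclei (adjusted p = 0.493) passed, only the cluster led by Ankrd1 and Csrp3, and with doublet calls kept the myofibre-like share did not pass (adjusted p = 0.0698; same test, Benjamini-Hochberg).

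**Figure D1:**
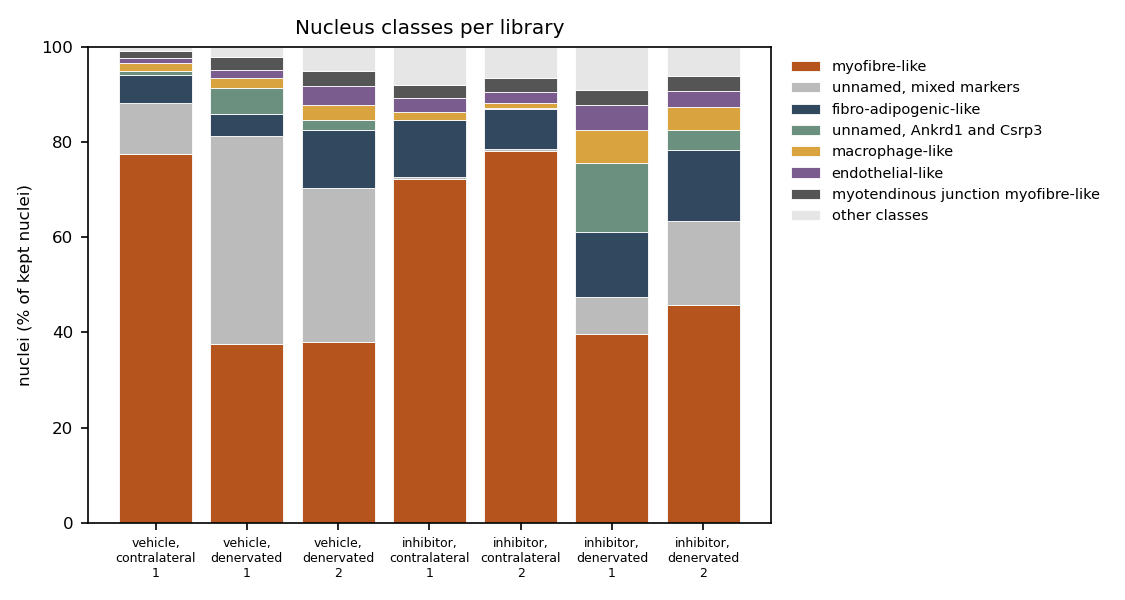
Percent of kept nuclei in each nucleus class (linear axis from 0 to 100), a stacked bar per library (n = 1 each); the classes with the smallest shares are summed as other classes. Myofibre-like nuclei lie between 37.6% and 45.8% in the 4 denervated libraries and above 72% in the 3 contralateral ones.

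A group of nuclei stayed outside these classes. A cluster with mixed markers held 36.7% of the nuclei of vehicle denervated muscle, 10.8% of vehicle contralateral, 11.8% of inhibitor denervated and 0.442% of inhibitor contralateral muscle. Tgfb3, Igfn1 and Hhipl1 were among its leading genes, and these genes differ between the legs, so its size is not read as the share of a cell type. A cluster led by Ankrd1 and Csrp3 held 0.794%, 3.42%, 0.0691% and 10.2% of vehicle contralateral, vehicle denervated, inhibitor contralateral and inhibitor denervated nuclei. Neither cluster entered the comparisons of myofibre-like nuclei. The myofibre-like nuclei themselves clustered by leg. The clusters made of denervated libraries held 96.4% of the vehicle and 93.6% of the inhibitor denervated myofibre-like nuclei, against 0.585% and 0.0914% of the contralateral ones. They also differed by treatment inside each leg. In denervated muscle a cluster with Igfn1 and Tgfb3 as leading genes held 86.6% and 54.7% of the vehicle and 22.6% and 43.5% of the inhibitor myofibre-like nuclei, and a cluster with Dlg2 and Kcnk5 held 9.75% and 41.8% against 72.1% and 48.6%. In contralateral muscle a cluster with Amd1 and Actr3b held 0.585% of the vehicle and 42.9% and 34.8% of the inhibitor nuclei, a cluster with Myoz1 and Arrdc2 2.05% against 26.5% and 17.9%, and a cluster with Klhl40 and Atf3 48.7% against 1.03% and 12.8%. A change summed over the class can therefore go with such shifts.

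Transection changed the muscle programme of the myofibre-like nuclei. Over both treatments, genes of the fetal and the extrasynaptic acetylcholine receptor rose in the 4 denervated libraries over the 3 contralateral ones. Chrng, the fetal gamma subunit, reached 120.0 ± 40.9 CPM against 0.883 ± 0.846 (SD, n = 4 and 3), and Chrna1, the alpha subunit, reached 129 ± 12.8 against 1.43 ± 0.657. Igfn1, a sarcomere-associated protein, rose from 4.98 ± 2.82 to 1479 ± 541 CPM, Kcnn3, a calcium-activated potassium channel, from 6.69 ± 7.16 to 669 ± 133, and Hhipl1 from 0.942 ± 0.815 to 406 ± 165. Mybpc2, the fast myosin-binding protein C, fell from 1287 ± 243 to 15.7 ± 11.7 CPM, Slc16a3, a lactate transporter, from 231 ± 73.6 to 2.67 ± 1.98, and Plin4, a lipid droplet coat protein, from 439.5 ± 182 to 6.88 ± 2.88. The edgeR quasi-likelihood test called 3111 of 11273 genes, 1365 higher and 1746 lower in denervated muscle.

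The other genes with the largest rises were Kcnk5, a potassium channel (log2 change 8.92 ± 0.53), Enpp3 (from 0.801 ± 0.797 to 200.4 ± 14.7 CPM), Aif1l (7.62 ± 0.57), Sln, the sarcolipin that regulates the calcium pump (7.63 ± 0.47), Uchl1, a deubiquitinase, and Hpgd. Uchl1 had 116 counts in denervated and 1 in contralateral libraries, a 382-fold ratio with a counting interval of 67.2 to 15220. The largest falls included Odf3l2, at least 120.1-fold lower with no counts in denervated libraries, and Perm1, a regulator of mitochondrial genes, with a ratio of 119 (interval 21.3 to 4723). Ratios were 143 (25.5 to 5646) for Chac1, 65.8 (22.4 to 319.7) for Dhrs7c and 59.8 (16.4 to 495.5) for Prima1. Gdap1 changed by -6.24 ± 0.40 on the log2 scale.

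Of the 18 measured genes of the neuromuscular junction list, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 change of 0.90. Chrnd rose by 7.01 ± 0.35, Utrn, the synaptic homologue of dystrophin, by 3.17 ± 0.29 and Musk, the receptor kinase that organises the synapse, by 1.16 ± 0.18. The list passed camera with an adjusted p of 0.000335, and had an adjusted p = 0.111 with an estimated correlation. Of 16 denervation-responsive regulators, 11 rose and 3 fell, with Ncam1, a neural adhesion molecule, at 5.81 ± 0.39 and Myog, the myogenic regulator myogenin, at 4.70 ± 0.39. That list passed camera (adjusted p = 0.000252; adjusted p = 0.14 with an estimated correlation). Hdac9, Dach2 and Mt1 were the members that fell, by 1.79, 2.88 and 1.68 on the log2 scale.

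Genes of energy metabolism fell, and so did the myofibre markers: 9 of 10 passed, with a median log2 change of -1.13, while the median of 5 fibro-adipogenic markers in the same sums was 1.06 and 1 of them rose. All 17 genes of glycolysis and glycogen breakdown fell, with a median log2 change of -2.86. Eno3, the muscle enolase, fell by 4.51, Pfkm, the muscle phosphofructokinase, from 1342 ± 490.2 to 138.5 ± 35.8 CPM and Pygm, glycogen phosphorylase, from 2420.0 ± 639 to 286 ± 41.5. Of 25 genes of oxidative phosphorylation and the TCA cycle, 24 fell (25 adjusted over the list alone; median -1.22), among them Idh2. Of 15 genes of fatty acid oxidation, 12 fell (13 over the list alone), including Lpl, lipoprotein lipase, by 3.79 and Ucp3 by 2.94. All 12 genes of the fast fibre sarcomere fell (median -1.19), and Myh4, the fast IIb myosin, went from 5358 ± 2289 to 1757 ± 233 CPM. Of 12 regulators of mitochondrial biogenesis, 7 fell (8 fell and 1 rose over the list alone), with Ppargc1a (PGC-1alpha) down by 2.61. Of 18 genes of the cAMP and immediate early response, 11 fell and 1 rose. Nr4a1, an activity-dependent nuclear receptor, fell by 4.58 and Sik1 rose by 2.57. Of the counts of the member Egr1, 68 of 73 in the vehicle contralateral library lay in the Klhl40 and Atf3 cluster. In the inhibitor contralateral libraries 46 of 61 and 140 of 175 did, and this list was not tested without that cluster. Of 8 polyamine genes, 5 fell, with Smox, spermine oxidase, down by 4.46. The camera adjusted p was 7.93e-13 for glycolysis, 5.94e-12 for oxidative phosphorylation, 5.71e-07 for fatty acid oxidation, 3.38e-06 for the fast sarcomere, 0.000206 for the cAMP list, 0.00165 for mitochondrial biogenesis and 0.00395 for polyamines. These 7 lists lay between adjusted p = 0.111 and adjusted p = 0.14 with an estimated correlation.

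The other 10 lists did not pass camera, although fry passed 12 lists, adding atrophy (adjusted p = 0.019), autophagy (adjusted p = 0.00752) and excitation-contraction coupling (adjusted p = 0.0101) to those 9. Among 18 genes of atrophy and its ubiquitin ligases, 4 fell and 0 rose (camera adjusted p = 0.0502). Trim63, the ligase MuRF1, fell from 1879 ± 413.5 to 612 ± 158 CPM, Nedd4l by 2.23 and Mstn, myostatin, by 2.75 on the log2 scale. Fbxo32, the ligase atrogin-1, had 1060.0 ± 303 CPM in denervated and 1781 ± 872 in contralateral libraries and did not pass (adjusted p = 0.196, edgeR quasi-likelihood test, Benjamini-Hochberg). In the prostaglandin list, 2 of 10 measured genes rose, Hpgd and Ptges, a prostaglandin E synthase (3.28 ± 0.47), and 2 fell, Abcc4, a prostaglandin exporter (-2.10 ± 0.19), and Ptgr2 (-0.62 ± 0.19). Ptger4, the EP4 receptor for prostaglandin E2, had too few counts to be tested. Of 17 autophagy genes 1 rose, Ctsl by 1.54, and 4 fell, Tfeb by 1.12. Of 32 proteasome genes 3 rose and 4 fell. In the remaining lists, 1 rose and 3 fell of 8 slow sarcomere genes, 3 and 7 of 14 genes of excitation-contraction coupling, 1 and 2 of 14 extracellular matrix genes, 1 and 2 of 8 neurotrophic genes, 1 and 0 of 10 inflammation genes, and 2 and 2 of 8 heat shock genes. Gdnf, a motor neuron trophic factor, rose by 3.21 ± 0.73 and Tgfb1 by 3.31 ± 0.72.

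**Figure D2:**
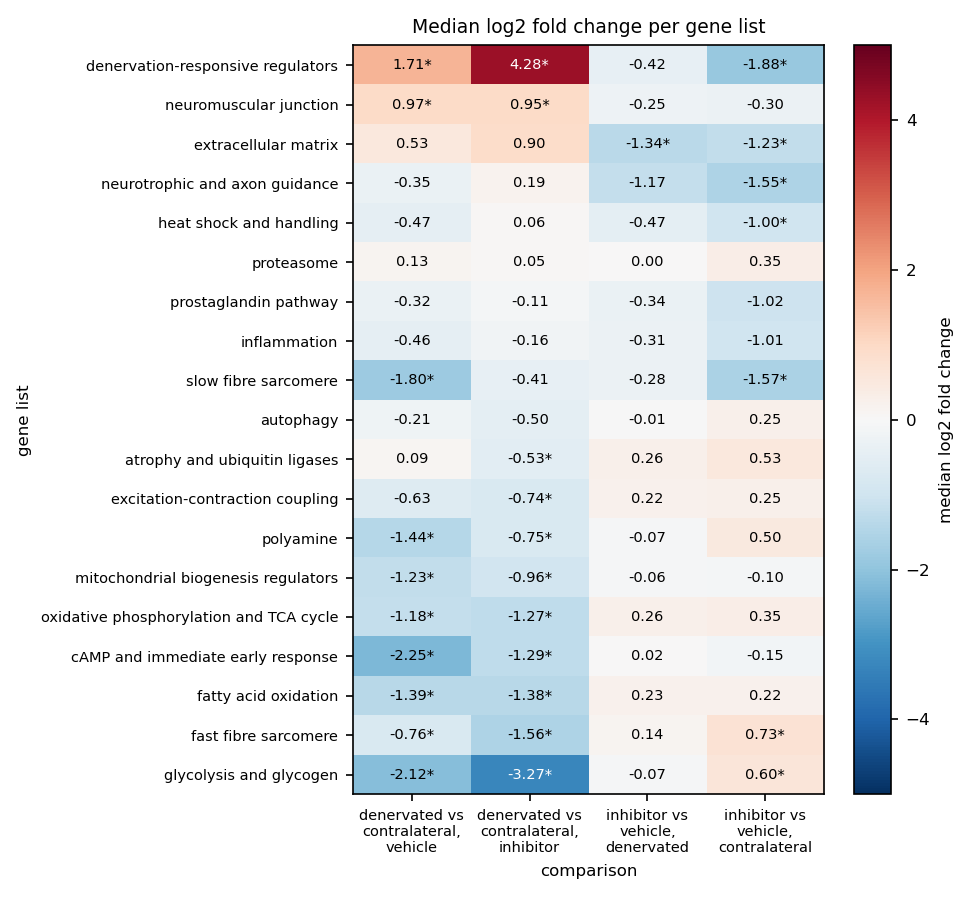
Median log2 change of each of the 19 gene lists in myofibre-like nuclei (colour scale from -5 to 5) in 4 comparisons, with the fitted change used for genes without counts in a group; an asterisk marks an adjusted p under 0.05 by camera with its preset correlation. Glycolysis has an asterisk below 0 for transection with either treatment.

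The comparison within vehicle-treated mice gives the response to transection without the inhibitor. It sets 2 denervated libraries against the lone contralateral one. Kcnk5 was at least 41-fold, Enpp3 at least 35-fold and Chrnd at least 11.3-fold higher, since none had a count in the contralateral library. Sln was at least 9.84-fold, Myog at least 7.4-fold, Eef1a1, an elongation factor, at least 5.64-fold, Uchl1 at least 4.93-fold, Lgals3 (galectin-3) at least 4.72-fold, Fibp at least 4.43-fold and Hlx at least 4.39-fold higher. Kcnn3 rose from 14.8 to 783 ± 6.79 CPM and Ncam1 from 31.4 to 847 ± 43.7 (n = 2). Mlf1 fell from 852.1 to 11.6 ± 2.87 CPM, Mybpc2 from 1122 to 13.7 ± 5.11, Ckmt2, the mitochondrial creatine kinase, from 347.5 to 6.84 ± 1.52, Rpl3l, the muscle form of a ribosomal protein, by 5.78 on the log2 scale and Plin4 from 231 to 4.68 ± 1.53. Dhrs7c was at least 24.7-fold, Perm1 at least 23.6-fold and Chac1 at least 20-fold lower, while Slc16a3 (ratio 94.2, interval 31.1 to 466.5) and the immediate early gene Fos (ratio 72.4, 18.8 to 618.1) kept 3 and 2 counts. Of the 41 Fos counts in the contralateral library 40 lay in the Klhl40 and Atf3 cluster, which held 48.7% of its myofibre-like nuclei. Without that cluster Fos had too few counts to be tested, and Egr1, which passed here (-2.54 ± 0.49, adjusted p = 0.00674), did not pass (-0.67, adjusted p = 0.785; edgeR quasi-likelihood test, Benjamini-Hochberg), so within vehicle the calls for these genes rest on that cluster in the lone library.

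In this comparison 1078 genes passed, 370 higher and 708 lower (edgeR quasi-likelihood test). Without the Klhl40 and Atf3 cluster 793 passed, 308 higher and 485 lower, and random removal of as many nuclei left a median of 789.5 (726 to 846 in 10 draws). Of 17 glycolysis genes 15 fell and of 25 oxidative phosphorylation genes 8 (17 and 15 adjusted over the list alone), and 7 of 18 neuromuscular junction genes rose (8 over the list alone). Camera passed 10 of the 19 lists, 2 upward and 8 downward, which had an adjusted p = 0.166 to adjusted p = 0.396 with an estimated correlation. Trim63 fell by 1.62 ± 0.27 (adjusted p = 0.00234) and Musk rose by 1.16 ± 0.30 (adjusted p = 0.0296; passed in 17 of 23 settings, with an adjusted p up to 0.0909), whereas Fbxo32 (0.12 ± 0.36, adjusted p = 0.886) and Myh4 (-0.62 ± 0.31, adjusted p = 0.252) did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg). Without vehicle denervated replicate 2 the number of genes was 488.

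With the inhibitor, 2 denervated libraries were set against 2 contralateral ones. Hhipl1 rose by 9.33 ± 0.56, Kcnk5 by 8.87 ± 0.55, Igfn1 by 8.36 ± 0.51, Chrng by 8.27 ± 0.51 and Aif1l by 8.13 ± 0.53 on the log2 scale. Kcnn3 went from 2.64 ± 2.02 to 555 ± 30.5 CPM (n = 2 each). Ces1d, a carboxylesterase, was at least 34.8-fold, Odf3l2 at least 95.4-fold and Prima1 at least 23.6-fold lower. Mybpc2 (-6.52 ± 0.56), Slc16a3 (-6.24 ± 0.39) and Plin4 (-5.85 ± 0.28) fell as well. Ratios were 111 (37.9 to 538.8) for Gdap1, 76.9 (13.7 to 3046) for Chac1 and 67.6 (18.6 to 559.2) for Slc15a5. Myh4 fell by 1.93 ± 0.26 (adjusted p = 0.000185), Trim63 by 1.48 ± 0.23 (adjusted p = 0.000473) and Fbxo32 by 0.87 ± 0.29 (adjusted p = 0.0418), while Musk rose by 1.17 ± 0.23 (adjusted p = 0.0024; edgeR quasi-likelihood test, Benjamini-Hochberg). Fbxo32 passed in 17 of 25 settings, with an adjusted p up to 0.304, so this call depends on the processing. The test called 3017 genes, 1317 higher and 1700 lower. All 17 glycolysis genes, 22 of 25 oxidative phosphorylation genes and 11 of 12 fast sarcomere genes fell (17, 24 and 12 adjusted over each list alone). Camera passed 11 lists, 2 upward and 9 downward, with an adjusted p = 0.149 to adjusted p = 0.472 with an estimated correlation. The count was 1703 without inhibitor denervated replicate 1, 1900 without replicate 2 and 1886 with DESeq2.

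Of the genes called with vehicle, 1033 of 1078 (95.8%) moved the same way with the inhibitor. The comparisons shared 320 higher genes, where 43.2 are expected of independent lists, and 558 lower genes, where 107 are expected. They have no library in common, although a single model gave the spread of both. Across all genes Pearson's r of the log2 changes was 0.54, over genes that are not independent replicates. Of the genes called in both comparisons, 4 moved in opposite directions.

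Open chromatin of the same nuclei changed at many shared regions. These regions held 66.8% to 70.7% of the peak counts in the denervated and 73.7% to 80.7% in the contralateral libraries. Median ATAC counts per myofibre-like nucleus were 30075 and 30555 in the inhibitor denervated libraries and 5781 to 11464.5 in the others. Whether such differences between libraries add to the calls was not tested. An intronic region of Kcnn3 (mm10, chromosome 3, 89578615 to 89579526) had 75.7 ± 4.40 CPM in the 4 denervated and 8.33 ± 2.72 in the 3 contralateral libraries, a log2 change of 3.26 ± 0.15 (adjusted p = 9.83e-10, edgeR quasi-likelihood test, Benjamini-Hochberg). A further Kcnn3 intronic region (89533729 to 89535368) rose by 2.40 ± 0.16, an exonic region of Igfn1 (chromosome 1, 135997312 to 135998206) by 2.34 ± 0.16 and the start of Aif1l (chromosome 2, 31949858 to 31950802) by 1.80 ± 0.15. An exonic region of Slc16a3 (chromosome 11, 120950493 to 120951478) fell from 96.25 ± 11.2 to 37.3 ± 1.53 CPM. Of 25814 regions tested, 12190 passed, 6212 more and 5978 less open in denervated muscle, and 20 of the 25 regions on named genes were among them. Of 1264 lower genes with a shared region at their start, 1130 (89.4%) had lower accessibility there, against 67.9% of all such genes, and of 946 higher genes 540 (57.1%) had higher accessibility, against 32.1%. Among the higher genes that region passed as more open for 273 and as less open for 167. Among the lower genes it passed as less open for 807 and as more open for 29.

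Within vehicle, 5467 regions passed, 2966 more and 2501 less open. An exonic region of Eef1a1 (chromosome 9, 78481383 to 78482299) rose from 13.6 to 94.4 ± 7.06 CPM and the start of Kcnk5 (chromosome 14, 20181309 to 20182260) from 18.3 to 48.7 ± 8.04, and 12 of 23 regions on named genes passed. With the inhibitor, 12301 regions passed, 6244 more and 6057 less open, with 23 of 25 on named genes. The intronic Kcnn3 region at 89578615 went from 6.76 ± 0.245 to 76.7 ± 3.90 CPM there. With regions that have a peak in at least 4 libraries, the balance tilted towards more open in all 3 comparisons of 49867 regions: 8844 more and 4648 less open over both treatments, 9336 and 2135 within vehicle and 10542 and 4729 with the inhibitor. A region without a peak in a library has no counts there.

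The comparison of inhibitor and vehicle in denervated muscle addresses the question in the series title. In 11273 genes it found 2 changes. Zbtb16, a zinc finger transcription factor also known as PLZF, rose from 176 ± 24.04 CPM with vehicle to 1103 ± 184 with the inhibitor, a log2 change of 2.63 ± 0.26 (n = 2 each). Tgfb3, a growth factor of the TGF-beta family, fell from 591 ± 71.8 to 143.5 ± 13.7 CPM, a change of -2.04 ± 0.21. Both had an adjusted p of 0.00307 (edgeR quasi-likelihood test, Benjamini-Hochberg), and both lost the call without vehicle denervated replicate 1 or without either inhibitor denervated replicate, where no gene passed. The changes kept their size over 24 settings, from 2.29 to 2.88 for Zbtb16 and from -2.22 to -1.89 for Tgfb3. Both also passed inside each of the 2 clusters that held most of these nuclei, fitted on the 4 denervated libraries: Zbtb16 by 2.34 ± 0.28 and Tgfb3 by -1.91 ± 0.25 in the Dlg2 and Kcnk5 cluster, and by 2.97 ± 0.32 and -2.04 ± 0.29 in the Igfn1 and Tgfb3 cluster, and no other gene passed in either (edgeR quasi-likelihood test, Benjamini-Hochberg). The clusters were drawn from the same counts. Zbtb16, which is known to respond to glucocorticoids, stood higher in contralateral muscle, at 2494 CPM in the vehicle and 3176 and 3263 in the inhibitor libraries, and transection lowered it with vehicle and with the inhibitor. Its inhibitor effect in contralateral muscle did not pass (0.37 ± 0.29, adjusted p = 0.453), and its interaction of 2.27 ± 0.37 did not pass either (adjusted p = 0.106, same test) but was positive in all 22 settings, at 1.61 to 2.57, and passed in 5. Tgfb3 was lower with the inhibitor in contralateral muscle as well (-2.05 ± 0.31, adjusted p = 0.00457, same test), with an interaction of 0.01 ± 0.26. That contralateral change passed in 21 of 23 settings. In the clusters led by Mybpc2 and Smox, by Myh2 and Ppara, and by Klhl40 and Atf3, each fitted alone, it was -1.67, -2.49 and -2.61, without passing. These fits rest on 8, 4 and 20 Tgfb3 counts in the vehicle contralateral library. Tgfb3 was also among the leading genes of the mixed-marker cluster that was larger in vehicle denervated muscle.

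No other gene passed in denervated muscle under the chosen settings. At an unadjusted p under 0.05 there were 1199 genes, DESeq2 called 26, and the count was 49 without inhibitor contralateral replicate 1 and 42 without replicate 2. It was 649 with the mixed-marker cluster put back, 137 over all nuclei and 127 with no low-count filter. Trim63 stood at 747 ± 49.6 CPM with the inhibitor and 478 ± 20.9 with vehicle (adjusted p = 0.395), Fbxo32 at 1240.0 ± 119.5 and 880.1 ± 362 (adjusted p = 0.548), and Musk at 1442 ± 187 and 1070.0 ± 169 (adjusted p = 0.516). Chrna1 differed by 0.00 ± 0.25 (adjusted p = 0.998), Myh4 by -0.01 ± 0.25 (adjusted p = 0.996) and Myog by -0.42 ± 0.32 (adjusted p = 0.659). Ppargc1a (1.35 ± 0.41, adjusted p = 0.345) and its partner receptor Esrrg (0.87 ± 0.21, adjusted p = 0.303) were higher in the mean without passing (edgeR quasi-likelihood test, Benjamini-Hochberg). Adjusted over the 12 regulators of mitochondrial biogenesis alone both passed (adjusted p = 0.0371 and adjusted p = 0.0187, same test), although 8 of the 12 were lower and the list did not pass camera (adjusted p = 0.755).

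Of the 19 lists, the extracellular matrix list was lower by camera (adjusted p = 2.28e-05; adjusted p = 0.383 with an estimated correlation). No member passed over all genes and 4 of 14 were lower when adjusted over the list alone, and all 14 had a negative change. Of 8 neurotrophic genes 1, Igf1, was lower over the list alone. Col6a3 changed by -2.78 ± 0.55, Col5a2 by -1.87 ± 0.63 and Adam12 by -1.68 ± 0.58. Fry does not set a list against the other genes, as camera does. Its adjusted p for the extracellular matrix list was 0.138, and it passed no list. Markers of other cell types in the same myofibre-like sums lay lower too, with a median log2 change of -1.47 for 5 fibro-adipogenic, -2.08 for 6 endothelial, -1.98 for 4 pericyte and -1.23 for 3 macrophage markers, none past the threshold, while the median of 10 myofibre markers was 0.13.

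Hpgd encodes 15-PGDH, the target of the inhibitor. In myofibre-like nuclei it had 0, 1 and 2 counts in the contralateral libraries, 4 and 41 in the vehicle denervated and 53 and 58 in the inhibitor denervated libraries. Over both treatments its level was 37.3 ± 28.2 CPM in denervated and 0.149 ± 0.137 in contralateral muscle, a ratio of 171 with a counting interval of 57.5 to 840 (adjusted p = 1.88e-06, edgeR quasi-likelihood test, Benjamini-Hochberg). With the inhibitor the ratio was 218 (72.6 to 1072). With vehicle it was at least 3.35-fold higher and did not pass (adjusted p = 0.0558, same test), with 7.68 and 29.5 CPM in the denervated libraries. This outcome depends on the processing, since Hpgd passed there in 10 of 23 settings. In denervated muscle the inhibitor libraries had 36.6 and 75.3 CPM, a log2 change of 1.31 ± 0.47 over vehicle that did not pass (adjusted p = 0.399, same test). Counted over all nuclei and scaled by total UMIs alone, the levels were 0.946 CPM in vehicle contralateral, 11.9 and 26.8 in vehicle denervated, 1.83 and 1.71 in inhibitor contralateral and 26.6 and 55.9 in inhibitor denervated libraries.

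**Figure D3:**
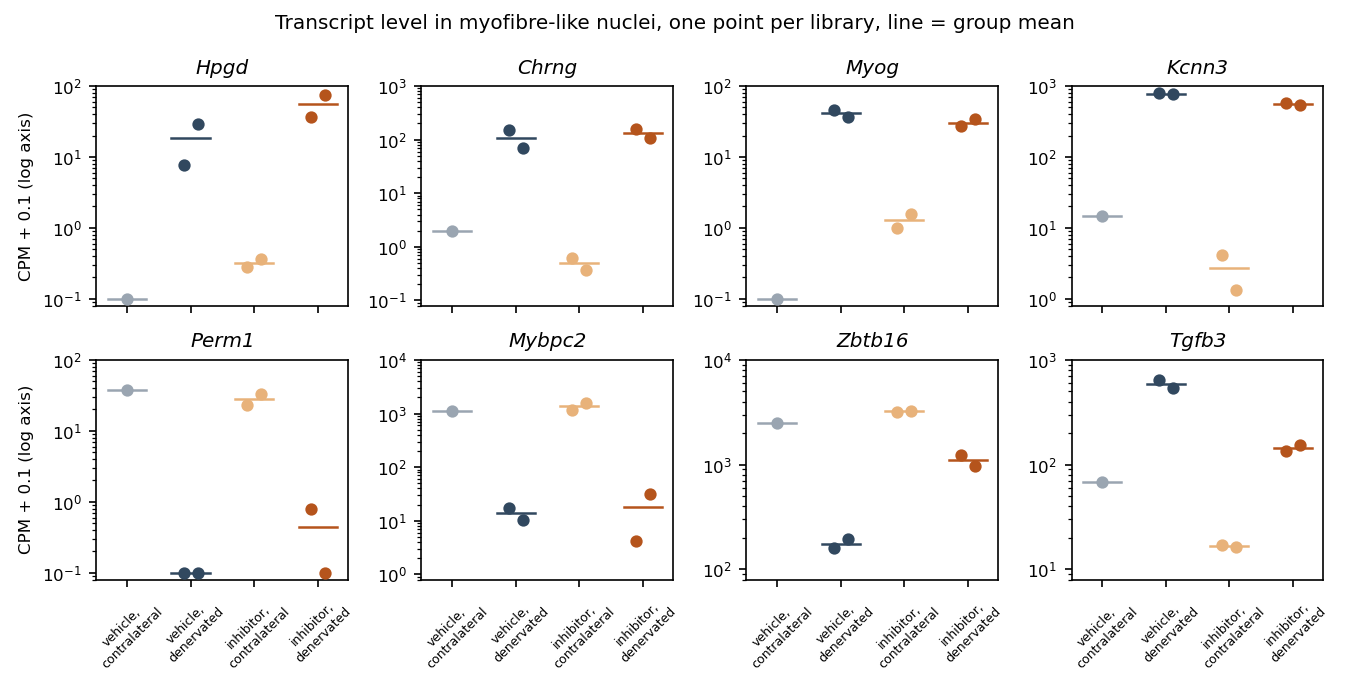
CPM plus an offset of 0.1 (log axis) of Hpgd, Chrng, Myog, Kcnn3, Perm1, Mybpc2, Zbtb16 and Tgfb3 in myofibre-like nuclei, a point per library and a line at the mean of each group (n = 1 vehicle contralateral and 2 in each other group). Hpgd lies at 7.68 CPM or more in all 4 denervated libraries and below 0.27 CPM in the 3 contralateral ones.

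Whether the inhibitor effect runs against the effect of transection was asked across the 1078 genes called with vehicle. In 54.7% of them the inhibitor effect in denervated muscle had the opposite sign. Both effects use the vehicle denervated libraries, which alone gives opposed signs: simulations without an inhibitor effect gave a median of 60.9% (59.4% to 63.6% over 50 simulations). The covariance of the changes was -0.26, nearer to 0 than the simulated -0.74 (-0.93 to -0.58). The opposed share thus lay below the range of these simulations. They drew each gene independently, while the genes of a real library can shift together. Their range can therefore be too narrow, and no conclusion is drawn from the difference.

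In contralateral muscle, 725 genes passed for inhibitor against vehicle, 195 higher and 530 lower, with 2 inhibitor libraries set against the lone vehicle one. With no low-count filter the balance turned, with 855 higher and 683 lower, so the excess of lower genes depends on the filter. Glis3, a transcription factor, was at 5.48 ± 2.73 CPM with the inhibitor and 251 with vehicle, Xdh, xanthine dehydrogenase, at 6.18 ± 1.73 and 183, Runx1, a transcription factor known to rise on denervation, at 51.5 ± 38.5 and 554.5, and Ankrd1, a stretch-responsive repressor, at 17.4 ± 12.6 and 213. Ubash3b fell by 5.97, Thbd, thrombomodulin, by 5.24, Il13ra1 by 5.02, Emp1 by 4.87, Cd300lf by 4.66, Hk1os by 4.64 and Trmt9b by 4.46 on the log2 scale. Arrdc2 rose from 27.7 to 517 ± 432 CPM, Fbxo32 from 813.3 to 2266 ± 339 and Myh4 from 2714 to 6680.0 ± 9.19. Fbxo32 and Myh4 each passed in 17 of 23 settings, with an adjusted p up to 0.228 and 0.269. Scnm1 was at least 4.02-fold and Rnf126 at least 3.91-fold higher. Rint1, Atxn7l3b, Lrrtm3, Sars2, Borcs7 and Btf3l4 had 1 or 2 vehicle counts and ratios of 10.8 to 13, the lowest bound of their counting intervals being 1.92.

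By list, 6 of 16 denervation-responsive regulators, 4 of 8 slow sarcomere genes, 3 of 14 matrix genes, 2 of 8 heat shock genes and 1 of 8 neurotrophic genes fell (10, 6, 5, 4 and 2 adjusted over each list alone). The neurotrophic gene was Igf1 (-3.78). In the other direction, 4 of 17 glycolysis and 2 of 12 fast sarcomere genes rose (4 and 5 over each list alone), such as Pfkm from 776 to 1624 ± 30.4 CPM. The camera adjusted p was 0.00139 for the denervation and slow sarcomere lists, 0.000939 for the matrix, 0.0036 for heat shock, 0.00703 for the neurotrophic, 0.0105 for the fast sarcomere and 0.0215 for the glycolysis list. All 7 were lost, at adjusted p = 0.254 to adjusted p = 0.562 with an estimated correlation. Nr4a1 rose by 1.57 ± 0.31 while Egr1 fell by 2.95 ± 0.44. A cluster led by Klhl40, Atf3 and Xirp1 held 48.7% of the myofibre-like nuclei of the vehicle contralateral library, 12.8% and 1.03% of the inhibitor contralateral ones, and at most 3.43% elsewhere. Without that cluster, which was drawn from the same counts, 11 genes passed, all of them among the 725. The 4 clusters with at least 20 nuclei in each contralateral library, fitted alone, gave 163, 5, 90 and 5 genes, in the clusters led by Mybpc2 and Smox, by Myh2 and Ppara, by Klhl40 and Atf3, and by Kcnn2 and Myh1. Arrdc2 was higher with the inhibitor in all 4 and passed in 2 (adjusted p = 9.78e-14 and adjusted p = 0.00096), Myh4 was higher by 0.72 to 1.86 and passed in 1 (adjusted p = 0.0494), and Fbxo32 was higher by 0.53 to 1.46 and passed in none (edgeR quasi-likelihood test, Benjamini-Hochberg). Single clusters hold fewer counts, so a lost call does not separate a shift between clusters from lower depth, and such a shift stays open as a part of these differences. In this comparison the median change was -2.18 for endothelial, -1.68 for pericyte, -1.90 for macrophage and -1.0 for fibro-adipogenic markers and 0.34 for myofibre markers, while 2 of 3 tenocyte markers were higher. The count was 1008 without inhibitor contralateral replicate 2, 441 without inhibitor denervated replicate 2 and 189 with only the 3 contralateral libraries.

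Whether the inhibitor effect differs between the legs was tested as an interaction. The edgeR quasi-likelihood test called 0 of 11273 genes, with 1194 at an unadjusted p under 0.05 and 52 by DESeq2. Ankrd1 had the change 3.86 ± 0.61 (adjusted p = 0.0987) and Tgfb2 1.96 ± 0.37 (adjusted p = 0.151; edgeR quasi-likelihood test, Benjamini-Hochberg). Myh4, Fbxo32 and Hpgd, which passed for transection with the inhibitor and not with vehicle, did not pass here: Myh4 had -1.31 ± 0.41 (adjusted p = 0.315), Fbxo32 -0.99 ± 0.46 (adjusted p = 0.481) and Hpgd -1.19 ± 4.66 (adjusted p = 0.948; same test). The count was 406 with the mixed-marker cluster put back and 133 with no low-count filter. Leaving out inhibitor contralateral replicate 1 gave 38 genes and leaving out replicate 2 gave 212. By camera, the denervation-responsive regulators and the slow sarcomere list (adjusted p = 0.0047 for each) and the heat shock list (adjusted p = 0.0272) were higher, all at adjusted p = 0.511 with an estimated correlation, and 7 of the 16 denervation-responsive regulators passed upward when adjusted over the list alone.

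Accessibility differed between inhibitor and vehicle at 9 of 25814 regions in denervated muscle, 3 more and 6 less open. None of the 18 regions on named genes passed. The nearest was an intronic region of Zbtb16 (chromosome 9, 48737176 to 48738139), at 42.8 ± 5.49 CPM with the inhibitor and 27.6 ± 2.57 with vehicle (adjusted p = 0.339, edgeR quasi-likelihood test, Benjamini-Hochberg). Leaving out vehicle denervated replicate 2 gave 1 region, leaving out inhibitor denervated replicate 1 gave 0 and leaving out its replicate 2 gave 6. In contralateral muscle 1819 regions passed, 611 more and 1208 less open, and 11 of the 31 on named genes. The start of Emp1 (chromosome 6, 135362353 to 135363288) was at 2.86 ± 0.863 CPM with the inhibitor and 13.45 with vehicle, and the start of Myh4 (chromosome 11, 67237235 to 67238079) at 81.8 ± 0.509 and 45.5. That count was 752 without inhibitor contralateral replicate 1, 1200.0 and 1186 without inhibitor denervated replicates 1 and 2. The direction depends on the set of regions. With a peak in at least 4 libraries, 2675 regions were more and 1444 less open in contralateral muscle and 706 more and 190 less open in denervated muscle, the opposite balance in both. A library without a peak in a region has no counts there. In each leg the vehicle libraries had fewer peaks than the inhibitor libraries, so a tilt towards more open can come from the peak calls.

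Fibro-adipogenic-like nuclei were the only other class with at least 20 nuclei in every library. The vehicle contralateral library held 52 of them and vehicle denervated library 1 held 54. At a clustering resolution of 2 these numbers were 16 and 26, so membership of the class depends on the clustering, and the minimum of 20 was not reached there. Within vehicle, 50 of 6051 tested genes fell in denervated muscle. With the inhibitor 17 genes rose, such as Thbs4, a matrix protein of injured tissue, from 10.2 ± 1.66 to 172 ± 3.75 CPM, Gpr39 by 3.54 ± 0.72 and Sfrp2, a secreted Wnt modulator, with a ratio of 79.05 (12.99 to 3241), and 10 fell. The genes with the largest falls were muscle transcripts: Mlf1 (at least 28.2-fold), Mylk2 (ratio 118, 19.3 to 4832), Mybpc2 (108, 28.3 to 920.8), Nctc1 (58.85, 14.7 to 512.6) and Myoz1 (56.5, 8.36 to 2415) with vehicle, and Mylk2, Ky, Eno3, Ckm and Asb2 with the inhibitor. These transcripts are not read as changes of this class, since its nuclei carry RNA of myofibres: Ttn, the myofibre gene titin, stood at 55.1% of its level in myofibre-like nuclei in the vehicle contralateral library, at 13.8% and 9.88% in the vehicle denervated, 7% and 24.4% in the inhibitor contralateral and 10.1% and 21.5% in the inhibitor denervated libraries. The same holds for the rise of Igfn1 with the inhibitor, whose level was 12.3% and 9.32% of that in myofibre-like nuclei. Ckm, another muscle transcript, stood at 147% of its myofibre-like level in the vehicle contralateral library and at 17.52% to 81.25% in the others. Whether myofibre nuclei placed in this class add to such RNA was not tested. No correction for this background was made. Inhibitor against vehicle gave 20 genes in contralateral muscle, all lower, among them Gpr39, Sel1l3, Slco5a1, Dysf and Ism1. The share of Ttn was highest in the vehicle contralateral library, so background RNA can bring falls here too, which was not tested. With the replicate number as a block 71 genes were higher and 140 lower, so the direction depends on the processing. In denervated muscle edgeR's quasi-likelihood test called 0, with 184 at an unadjusted p under 0.05. These counts rest on single libraries. Without vehicle denervated replicate 1 they were 0 within vehicle, 3 with the inhibitor and 2 in contralateral muscle, without vehicle denervated replicate 2 they were 0 in each, without inhibitor contralateral replicate 1 they were 149, 80 and 30, and without its replicate 2 they were 139, 55 and 255. Without inhibitor denervated replicate 1 they were 89 within vehicle and 43 in contralateral muscle, and without its replicate 2 they were 6 with the inhibitor.

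Macrophage-like nuclei reached 20 in the 6 libraries other than the vehicle contralateral one. There 24 of 2066 genes passed between the legs with the inhibitor. The 22 that were lower in denervated muscle included the myofibre transcripts Asb2, Mylk2, Mybpc2, Pygm, Ckm and Ttn, which background RNA of myofibres can bring. Ttn was at 34.3% and 21.6% of its myofibre level in the contralateral and 8.82% and 4.32% in the denervated libraries with the inhibitor. Between inhibitor and vehicle in denervated muscle the edgeR quasi-likelihood test called 0, with 116 at an unadjusted p under 0.05.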

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

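The tests of little RNA, of doublets and of lower depth in the lone library, and the counts over other splits of the libraries, were chosen only after the result was seen.

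The transection effect on chromatin accessibility differed between inhibitor and vehicle at 344 of 25814 regions (edgeR quasi-likelihood test of the interaction), 282 with the more positive effect under the inhibitor and 62 with the more negative; a difference between groups raised this result. The direction depends on the set of regions, since with a peak in at least 4 libraries 1700 were more positive and 2285 more negative. In that set a library without a peak in a region has no counts there. The count was 203 and 405 without inhibitor contralateral replicates 1 and 2, 5 and 8 without inhibitor denervated replicates 1 and 2, and 174 without vehicle denervated replicate 2, while no gene passed the same test on RNA.

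Hpgd was also seen in nuclei that no comparison uses. The mixed-marker nuclei of denervated legs, summed over libraries, held 93 Hpgd counts in 4243397 UMIs, or 21.92 CPM (counting interval 17.7 to 26.8). Those of contralateral legs held 1 count in 379888 UMIs, or 2.63 CPM (0.0667 to 14.7).

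Mixed-marker nuclei were 10.8% and 36.7% of vehicle contralateral and denervated nuclei, against 0.442% and 11.8% with the inhibitor. The tables argue against nuclei with little RNA, since their median UMI count was at least 1.704 times that of myofibre-like nuclei in every vehicle library. In the inhibitor contralateral libraries, with 16 such nuclei each, the ratio was 0.573 and 0.658. Mixed-marker nuclei had a higher median mitochondrial percent than myofibre-like nuclei in every library, such as 0.659 against 0.132 in the vehicle contralateral one. Doublets from loading would be most frequent in the library with the most barcodes, which had the lowest share, 0.3991%, but in the vehicle libraries these nuclei had 2.84 to 4.52 times the ATAC counts of myofibre-like nuclei and higher doublet scores (0.032 against 0.0184 in the contralateral one), so nuclei clumped before loading stay open, untested. A library-wide difference in RNA composition stays open and met its test: the ribosomal-RNA-like transcript Gm42418 took at least 3.66% of UMIs in fibro-adipogenic-like nuclei of each vehicle library and at most 3.15% in each inhibitor library, a ratio of 1.164. Such a difference could come from preparation or from treatment, and the design does not separate these.

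In contralateral myofibre-like nuclei the inhibitor comparison gave 725 genes. The tables argue against lower summed depth of the lone vehicle library as the whole cause. With every library thinned to the smallest 535 genes passed, 424 of them among the 725. Thinning does not even out depth per nucleus. The median was 774 UMIs per myofibre-like nucleus in that library and 2370 and 2283 in the inhibitor contralateral ones. With at least 1000 UMIs per nucleus 308 genes passed, so lower depth per nucleus stays open. The share of nuclei of the Atf3 and Klhl40 cluster stays open and met its test: 11 genes passed without it, while random removal of as many nuclei left a median of 388 (287 to 505 in 10 draws). The cluster was drawn from the same counts, so its removal takes out differences in expression whatever their cause. This test cannot tell a shift in shares from a treatment effect. With each inhibitor contralateral library set as the lone one, 0 genes passed. The vehicle and the other inhibitor library then formed a single group, so a difference between treatments counted as spread, which lowers the number of calls. This test therefore cannot decide the question. One contralateral library standing apart cannot be told apart from a treatment effect with a lone, pooled vehicle library. No biological explanation beyond treatment was tested.

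Of 34 fitted splits of the 7 libraries into 4 and 3, only the split by leg gave as many genes as it did, 1 split with 3111, the next highest giving 609. In accessibility 1 of 34 splits, again that by leg, gave 12190 regions, the next highest giving 3726.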

How the results depend on the processing

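The alternatives with at least 200 UMIs, with the mixed-marker or the Ankrd1 and Csrp3 cluster, without the Atf3 and Klhl40 cluster, without ribosomal-RNA-like transcripts, with thinned counts, with resolution 2.0 for the myofibre comparisons, with covered length, without the vehicle contralateral library, the block on accessibility and other classes, single myofibre-like clusters, and shares with unnamed clusters counted as myofibre-like were chosen only after the result was seen. Of 1203 values for 9 named genes other than Hpgd under other settings, 1106 kept their direction and side of the threshold, 34 no longer passed, 12 newly passed and 51 changed sign. With Hpgd, of 1336 values 1219 kept both, 34 no longer passed, 24 newly passed and 59 did not keep their sign, none of them past the threshold in the main or the other setting. Where a value below moved, the cause was not tested unless the setting leaves out libraries or nuclei.

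With the mixed-marker cluster the counts of genes were 5101 for transection with the inhibitor, 649 and 4732 for the inhibitor in denervated and contralateral muscle, and 406 for the interaction. With no low-count filter they were 127 and 1538 for the inhibitor in denervated and contralateral muscle and 133 for the interaction, and over all nuclei 137, 2796 and 1. With DESeq2 (Wald test) they were 1886 for transection with the inhibitor, 26 for the inhibitor in denervated muscle and 52 for the interaction. Thinned counts gave 1827 for transection with the inhibitor and 14 for the interaction. For the inhibitor in contralateral muscle, at least 1000 UMIs per nucleus gave 308, only the libraries of the 2 groups 189, no Atf3 and Klhl40 cluster 11, and single clusters 163, 5, 90 and 5. The interaction gave 2 genes with doublet calls kept, 4 with at least 200 UMIs, 1 at resolution 2.0 and 1 with the Ankrd1 and Csrp3 cluster.

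Regions with a peak in at least 4 libraries gave 11471 within vehicle, 896 and 4119 for the inhibitor in denervated and contralateral muscle and 3985 for the interaction, and covered length as an offset gave 5 for the inhibitor in denervated muscle. With an estimated correlation camera passed 0 lists in all 6 contrasts, and fry passed 0 for the inhibitor in denervated muscle and 0 for the interaction. The larger set of regions turned the balance for the inhibitor in contralateral muscle (2675 more and 1444 less open), in denervated muscle (706 and 190) and for the interaction (1700 more positive and 2285 more negative). Libraries without a peak in a region have no counts there. For shares, 1 class passed for the leg at 1000 UMIs, 2 at 200, 0 with the mixed-marker cluster counted as myofibre-like and 1 with both unnamed clusters, and for the inhibitor in contralateral muscle 3 passed at resolution 2.0, 2 with doublet calls kept and 4 at 200 UMIs.

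Within vehicle, where Hpgd had 0 counts in the contralateral library, only the bound of at least 3.35-fold holds, and log2 values are fitted ones without an upper limit. The fit passed in 10 of 23 settings. Among them were 8.64 with no low-count filter, 8.92 with doublet calls kept, 7.13 with only the libraries of the 2 groups, 8.88 at 200 UMIs, 3.98 with the mixed-marker cluster and 6.42 with thinned counts. Between inhibitor and vehicle in denervated muscle it passed at 1.38 with no low-count filter and 1.37 with the mixed-marker cluster. Its interaction was -1.19 ± 4.66 and had the other sign with DESeq2 (2.15), over all nuclei (0.0436), with the mixed-marker cluster (3.27) and with thinned counts (1.65). Its contralateral inhibitor effect was -1.90 with the mixed-marker cluster, -0.65 with DESeq2 and 0 with thinned counts.

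The other changes of sign were all in values that never passed. Fbxo32 within vehicle was -0.0734 over all nuclei, -0.33 without the Atf3 and Klhl40 cluster and -0.379 to 0.442 with a library left out. For the inhibitor in denervated muscle, Chrna1 was -0.038 with at least 20 CPM, -0.116 over all nuclei, -0.0302 with only the libraries of the 2 groups, -0.0392 at 200 UMIs, -0.080 at resolution 2.0, -0.0871 with the Ankrd1 and Csrp3 cluster, -0.0206 without the Atf3 and Klhl40 cluster, -0.0781 with thinned counts and -0.11 to 0.17 with a library left out. Myh4 was 0.0197 with DESeq2 size factors, 0.0653 with no low-count filter, 0.199 over all nuclei, 0.441 with the mixed-marker cluster, 0.0193 with DESeq2 and -0.161 to 0.153 with a library left out, where Chrng ranged from -0.17 to 0.988. For the inhibitor in contralateral muscle at 1000 UMIs and without the Atf3 and Klhl40 cluster, Chrna1 was 4.57 and 4.51 and Chrng 3.09 and 3.13, and in the interaction -4.51 and -4.53, and -2.72 and -2.75. In the interaction Tgfb3 was -0.209 with no low-count filter, -0.754 at 1000 UMIs, -0.283 over all nuclei, -0.166 without the Atf3 and Klhl40 cluster, -0.058 with thinned counts and -0.0877 to 0.256 with a library left out. Musk was -0.209, -0.0826, -0.16 and -0.712 under the first 4 of these, -0.0419 with doublet calls kept, -0.157 with the mixed-marker cluster and -0.0349 to 0.281 with a library left out, and Trim63 was -0.0778, -0.0153, -0.108 and -0.0521 under the same 4 and -0.0429 with the mixed-marker cluster.

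Titles share replicate numbers without naming shared animals, and deviations of same-numbered libraries correlated at -0.063, -0.17 and 0.178 over 5780 genes. With the number as a replicate block, 2886, 1100.0, 3003, 2, 721 and 2 genes passed for both treatments, vehicle, inhibitor, inhibitor in denervated, inhibitor in contralateral and interaction, and Hpgd within vehicle passed at a fitted 8.49. Camera passed 12 lists for both treatments with this block, adding atrophy, excitation-contraction coupling and the slow sarcomere. In fibro-adipogenic-like nuclei the replicate block gave 192, 120.0, 4, 211 and 74 genes for vehicle, inhibitor, inhibitor in denervated, inhibitor in contralateral and interaction.

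Leaving out 1 library at a time, a lone library being assumed to vary like the others, gave 2154 to 2928 genes for both treatments, 488 to 1393 within vehicle, 1703 to 2911 with the inhibitor, 0 to 49 and 441 to 1008 for the inhibitor in denervated and contralateral muscle, and 0 to 212 for the interaction. Regions ranged over 9338 to 12309, 3920.0 to 5325, 9260.0 to 13256, 0 to 12, 752 to 2554 and 5 to 405 in that order. Fibro-adipogenic-like counts ranged over 0 to 149, 0 to 80, 0 to 3, 0 to 255 and 0 to 97 from the vehicle comparison on, and fitted Hpgd values, bounded on 1 side only where they rest on the vehicle contralateral library, over 7.17 to 8.15, 7.44 to 9.45, 7.14 to 8.14, 0.85 to 2.78, 1.77 to 2.63 and -1.78 to 0.20 in the full order. Depth is limited in vehicle contralateral and vehicle denervated library 1, with 637140 and 491329 myofibre-like UMIs and medians of 774 and 926 per nucleus.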

Other observations

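The clock gene and glucocorticoid lists were chosen only after values of several members had been seen, and the tests over both legs without ribosomal-RNA-like transcripts or with thinned counts only after the result was seen.

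Genes of the circadian clock differed between inhibitor and vehicle over both legs in myofibre-like nuclei. Npas2, a partner of the clock activator, was at 49.9, 46.1 and 30.9 CPM in the vehicle libraries and at 4.43, 5.12, 12.4 and 9.09 in the inhibitor libraries (log2 change -2.54 ± 0.28, adjusted p = 0.0015, edgeR quasi-likelihood test, Benjamini-Hochberg). Dbp rose by 1.78 ± 0.33, Per3 by 1.04 ± 0.20, Per2 by 0.88 ± 0.20 and Nr1d1 by 0.98 ± 0.25. Of 15 measured clock genes, 7 passed over both legs, 3 in contralateral muscle and 0 in denervated muscle, where 7 had an unadjusted p under 0.05. Among 16 genes known to respond to glucocorticoids, 7 passed, with Fkbp5 up by 1.97 ± 0.33, Arrdc2 by 4.08 ± 0.73, Tsc22d3 by 0.83 ± 0.22 and Sgk1 by 0.75 ± 0.20, while Mt1 fell by 1.11. Zbtb16, which passed in denervated muscle, belongs to this list and passed over both legs (adjusted p = 0.00291) but not in contralateral muscle alone (adjusted p = 0.453, edgeR quasi-likelihood test, Benjamini-Hochberg). Over both legs 953 genes passed in these nuclei, 311 higher and 642 lower, and 14 in fibro-adipogenic-like nuclei.

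Ribosomal-RNA-like transcripts or depth stay open as a part of the clock pattern: over both legs 7 clock genes passed without those transcripts and 5 with thinned counts, and in contralateral muscle 3 and 2. The prediction set a limit of 1.5 times, which 2 against 3 just meets, and the limit was read as strict only after that value was known, so the explanation is left open rather than excluded. Time of day of tissue collection was tested in fibro-adipogenic-like nuclei, where 100% of the 13 measured clock genes moved in the sign seen in myofibre-like nuclei, past the 80% set for it. In the sign expected of a shifted clock the share was 76.92%, and 0 passed the adjusted threshold. Npas2 changed there by less than its standard error, while Per3 changed by more. This class held 52 nuclei in the vehicle contralateral library, and 16 at a clustering resolution of 2. Its nuclei carry RNA of myofibres, which can bring the same signs. Whether it did was not tested, so the shared sign does not show a clock shift in a second class. Time of collection stays open, and so does an effect of treatment on both classes, which would give the same values. Groups collected at different hours could give such a pattern, and collection times were not given in the sample labels.

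Myotendinous-junction-like nuclei were 1.47% of the vehicle contralateral library and 2.63% to 3.21% of the other 6. Schwann-like nuclei were 0 in the vehicle contralateral library, 0.256% and 0.374% in vehicle denervated, 0.248% and 0.0748% in inhibitor contralateral and 0.774% and 0.784% in inhibitor denervated libraries.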
